A study of Mus musculus with 10 samples.

How the data were processed

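RNA sequencing counts from quadriceps of 10 wild-type C57BL mice were analysed, 5 in the Control group and 5 in the 1C-MIM group, with groups taken from the titles and treatment labels. Per the labels, the material was total RNA, and a company, Active Motif, harvested the RNA and prepared the libraries. Cages of at most 5 mice received 150 mL of water every other day. No label names a litter, cage, sex, collection time or library batch.

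The deposited tables hold, per the file headers, a count, an FPKM and a TPM for each of 33984 RefSeq transcripts, with a table for each animal. The submitters' processing notes name Trim Galore 0.6.7, Salmon 1.5.2, STAR, SAMtools 1.15.1, Picard 2.27.4, StringTie 2.2.1, bedtools 2.30.0, featureCounts, Subread 2.0.1 and DESeq2 1.28.0 and the genome build GRCm39, with no role or order for any tool. The deposited count values are whole numbers with no normalization by the authors, and a read that fits several isoforms is counted for each of them. For example, the 8 Tnnt3 transcripts had 689716 to 689942 counts in Control 1. Of 5261 symbols with several transcripts, 3084 had at least 1000 reads over all libraries. In 91.1% of these 3084 the next transcript held at least 80% of the counts of the first. The deposited FPKM values, made by the authors per kilobase of transcript and per library total of transcript counts, served only to recover transcript lengths. The deposited TPM values, scaled by the authors for transcript length to the same total in each library, were not used. Filters and strandedness of the counting are not given in the sources used here. No coordinates are given, since the reference annotation at hand is of build GRCm38 and was used only for gene names and GC content; it gave GC content for 23498 symbols.

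Because isoform counts overlap, each symbol was represented by the transcript with the largest total over all libraries, which gave 24063 symbols, of which 19459 had a read. Between 45.3 and 47.4% of a library's transcript counts lay on other transcripts and were left out. Near-identical genes such as Amd1 and Amd2 still share reads, and 77 genes had counts within 1% of another symbol's in the tables; none of these is a gene named singly in the results. Library totals of 28521254 to 31771296 counts set the precision, and counting error is only part of the spread between animals that the tests use.

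Genes were filtered with filterByExpr and scaled with TMM factors in edgeR 4.0.16 (R 4.3.3), which left 13880 genes. The groups were compared with edgeR's quasi-likelihood F test with robust dispersion, and genes with a Benjamini-Hochberg adjusted p under 0.05 over all tested genes were called. Expression is given in counts per 1000000 (CPM) scaled by TMM. For log2 values a prior count of 2 was used. The share of variance between the groups was tested by exact permutation over 252 assignments, one-sided. Gene lists, 38 in all, covered one-carbon pathways, muscle fibre types, energy metabolism, stress responses and the cell types a muscle sample can hold. They were tested with camera from limma 3.58.1 with a preset correlation of 0.01 where at least 5 members were measured, and adjusted over the 37 lists that had these. The list of mitochondrially encoded genes could not be tested, since the tables hold 0 such symbols.

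The genes named singly follow a rule. Among called genes with all 5 1C-MIM libraries on the same side of the Control mean and a mean log2 CPM of at least 0, leaving out predicted genes and pseudogenes, the 12 with the largest increase and the 12 with the largest decrease were named. To these came the 3 members with the smallest p of each called list and of the folate, serine and glutathione, polyamine and methylation enzyme lists, and 5 sex-linked genes, of which Xist had too few reads to be tested. Of the 78 genes this gave, 76 were past the threshold. The groups, the tests, the lists, this rule and most of the alternatives were fixed before the data were examined.

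The alternatives fixed in this way were DESeq2 size factors, upper-quartile factors and library totals as scaling; no filter and a filter of 1 CPM in 5 libraries; DESeq2 1.42.0, limma-voom with and without sample quality weights, and a prior without robust estimation; replicate number as a block, the series of the animal number as a block, and 1 surrogate variable from sva 3.50.0; each library left out in turn; an adjusted p under 0.1 and a fold change of at least 1.5; for the lists, camera with an estimated correlation and fry; for the variance share, the 1000 most variable genes. Sex as a block did not apply, since all libraries showed the same pattern, and the sex-linked genes were left out instead. Chosen after seeing the data were counts summed over transcripts, each transcript tested alone, removal of each library's trend with transcript length or with length and GC content (natural splines with 3 inner knots, entered as offsets), and leaving out Control 1 and Control 5 together. The real grouping was also compared with other splits of the 10 libraries, 100 of the 126 possible splits with the real one among them.

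The procedure was tested on simulated data with the same design and 200 changed genes, all drawn from genes with a mean of at least 1 CPM. It recovered 83.6% of the genes changed 1.5-fold and 98.5% of those changed 2-fold, and 5.6% of its calls were unchanged genes. The recovery of genes below 1 CPM was not tested. These data had genes independent of each other and no length trend, unlike the real libraries. A simulated length trend without any changed gene gave 759 calls without the length correction and 0 with it. That simulation checks only that the correction removes a trend of the simulated kind. It does not estimate how many calls the trend in the real libraries produced. The slopes of the real libraries were taken from deviations from each gene's mean over all libraries. Per doubling of length, they varied within each group (SD 0.055 in Control and 0.059 in 1C-MIM). Tables were prepared in Python 3.11.15 with numpy 2.4.6 and pandas 2.3.3, and plots were drawn with matplotlib 3.10.9.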

Results

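RNA from mouse quadriceps muscle was sequenced in 10 libraries, 5 from animals that drank the facility's water (Control) and 5 from animals whose water carried a supplement called 1C-MIM in the labels. The series asks what a metabolite intervention does to gene expression in muscle; the composition of 1C-MIM is not given in the sources used here. The animals were wild-type C57BL mice aged 17 to 20 months, and the supplement was given for 1 to 3 months. A tibialis anterior muscle of the same mice had been injured, and the RNA came from quadriceps that had not been injured. The time between injury and collection is not given in the sources used here. The deposited names number the libraries as separate animals, so n counts animals.

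After 1 transcript was kept per gene symbol, the Control libraries held 28521254, 30145512, 30595120, 30082082 and 29902703 counts (Control 1 to 5). The 1C-MIM libraries held 30800881, 29108462, 31771296, 29963070 and 30758532 counts (1C-MIM 1 to 5). Between 16832 and 17331 genes had at least 1 read in a library. Myh4, the myosin heavy chain of the fastest mouse fibres, was the most abundant gene in every library with 5.71 to 8.08% of counts, and the 10 most abundant genes together held 27.0 to 29.5%. Among Controls the share of these 10 genes was 29.5% in Control 5 and 27.0 to 27.3% in the others. All libraries carried the Y-linked transcripts Ddx3y (976 to 1789 reads), Eif2s3y (927 to 1432), Kdm5d (208 to 417) and Uty (125 to 303). Xist had 10 reads in Control 1, the library with neural transcripts described later, and 0 to 2 in the others. The libraries thus showed a single, male-typical pattern.

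The comparison of 1C-MIM with Control asked which quadriceps genes differed with the supplement. In supplemented muscle, 22 of 25 macrophage genes, 7 of 11 lymphocyte genes, 19 of 32 matrix genes, 12 of 21 cell cycle genes, 12 of 25 immediate early genes and 10 of 23 embryonic myofibre genes were lower, and 10 of 20 circadian clock genes were higher. As lists these passed camera at a preset correlation, but not with an estimated correlation (adjusted p = 0.0938 for the clock and 0.444 to 0.545 for the others). Of 13880 genes tested, 1357 were higher and 1642 lower in 1C-MIM (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p under 0.05), together 21.6%. Large changes were mostly decreases: 26 called genes were at least 2-fold higher and 215 at least 2-fold lower. The groups did not overlap at all in 14.6% of the genes, where chance gives 0.79%, and 1805 of the called genes were among these. The difference between the group means accounted for 36.7% of the variance of log2 expression (exact permutation test, one-sided p = 0.0079, the smallest that 252 assignments allow). On the first principal component, with 42.5% of the variance, the Control libraries scored -38.6 to -4.5 and the 1C-MIM libraries 10.6 to 25.3. With library totals alone as the scaling, 606 genes were higher and 2896 lower, so the balance of the directions rests on the composition factors. Without Control 1, which holds neural transcripts, and Control 5, which lay farthest out on the first component, 832 were higher and 976 lower. Leaving out Control 4 gave 902 higher, 1C-MIM 3 gave 843 and 1057 lower, and 1C-MIM 4 gave 739 and 941 lower.

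**Figure D1:**
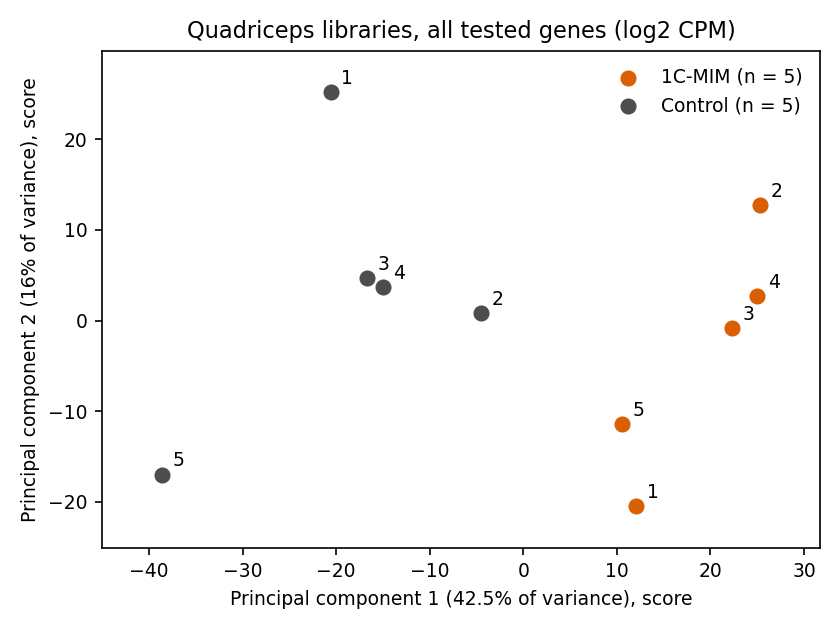
Each point is a library, placed by its scores on the first and second principal components of log2 counts per 1000000 over all 13880 tested genes, with axes labelled by the share of variance (42.5% and 16%). The 5 Control libraries lie at -38.6 to -4.5 on the first component and the 5 1C-MIM libraries at 10.6 to 25.3.

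The largest decreases on the log2 scale were in Tmem8c, Socs1 and Socs3. Tmem8c (myomaker, current symbol Mymk), the membrane protein that myoblasts need to fuse, fell from 4.18 ± 1.92 to 0.308 ± 0.211 counts per 1000000 (CPM; mean ± SD, n = 5 per group), a log2 fold change of -3.73 (SE 0.43, edgeR adjusted p = 0.000292). Socs3, a feedback inhibitor of cytokine signalling, fell from 28.1 ± 11.1 to 2.71 ± 0.357 CPM (log2 fold change -3.37, SE 0.25, edgeR adjusted p = 4e-05), and its relative Socs1 fell by 3.72 on the log2 scale (SE 0.68). The metallothionein Mt2 fell from 47.2 ± 7.0 to 9.47 ± 1.1 CPM (log2 fold change -2.32, SE 0.11, edgeR adjusted p = 2.11e-07). Other large decreases were in Timp1, an inhibitor of matrix metalloproteinases (-2.78, SE 0.32), and Tnni1, the slow troponin I (-2.62, SE 0.24). They were followed by the B-cell chemokine Cxcl13 (-2.57, SE 0.62), the macrophage elastase Mmp12 (-2.30, SE 0.37), the microglia and macrophage receptor Trem2 (-2.23, SE 0.21), Mdfi (-2.11, SE 0.22) and Pnmal2 (-2.11, SE 0.29). Tubb2b, a tubulin of developing neurons, fell from 4.85 ± 6.18 to 0.995 ± 0.205 CPM, but its size rested on Control 1 with 15.9 CPM, and the log2 fold change was -1.07 without that library (edgeR adjusted p = 0.00491). Its call was lost when several other single libraries were left out (adjusted p of up to 0.104), and that of Cxcl13, whose groups overlapped, was lost with limma-voom and with 1 surrogate variable (adjusted p = 0.0597 and 0.0545).

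Among the genes that rose, the largest change was in Npr3, the clearance receptor for natriuretic peptides, which went from 6.62 ± 1.3 to 20.2 ± 5.4 CPM (log2 fold change 1.61, SE 0.19, edgeR adjusted p = 0.000325). The adipocyte hormone gene Lep followed at 1.42 (SE 0.32), with overlapping groups and 1 Control library, Control 2, well above the other Controls. Next came Igfn1, a large protein of the skeletal muscle Z-disc (1.39, SE 0.17). It was followed by the cadherins Cdh4 (1.27, SE 0.11) and Cdh23 (1.00, SE 0.13; 0.65 with the length trend described later removed), and Nhs (1.26, SE 0.25). Other increases were in Prima1, the membrane anchor of acetylcholinesterase (1.13, SE 0.16), Odf3l2 (1.13, SE 0.16), the T-cell costimulatory receptor Cd28 (1.07, SE 0.11), Btnl9 (1.05, SE 0.23; overlapping groups), the peptide transporter Slc15a2 (1.00, SE 0.26; overlapping groups) and Shroom4 (0.97, SE 0.31). By the rule that chose these 12 higher and 12 lower genes, all 5 1C-MIM libraries lay on the same side of the Control mean. The call of Shroom4 (edgeR adjusted p = 0.0406) was lost without any of Control 3, Control 4, 1C-MIM 2, 1C-MIM 3 or 1C-MIM 4 (adjusted p = 0.0529 to 0.0968) and with that trend removed, although the fold change stayed similar (0.89, SE 0.28, adjusted p = 0.0536). Control 5 lay far below the other Controls for this gene. The call of Lep was lost with replicate number as a block and without Control 1 and Control 5 together (adjusted p = 0.0512 and 0.0964). That of Slc15a2 was lost with 1 surrogate variable (adjusted p = 0.0891).

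**Figure D2:**
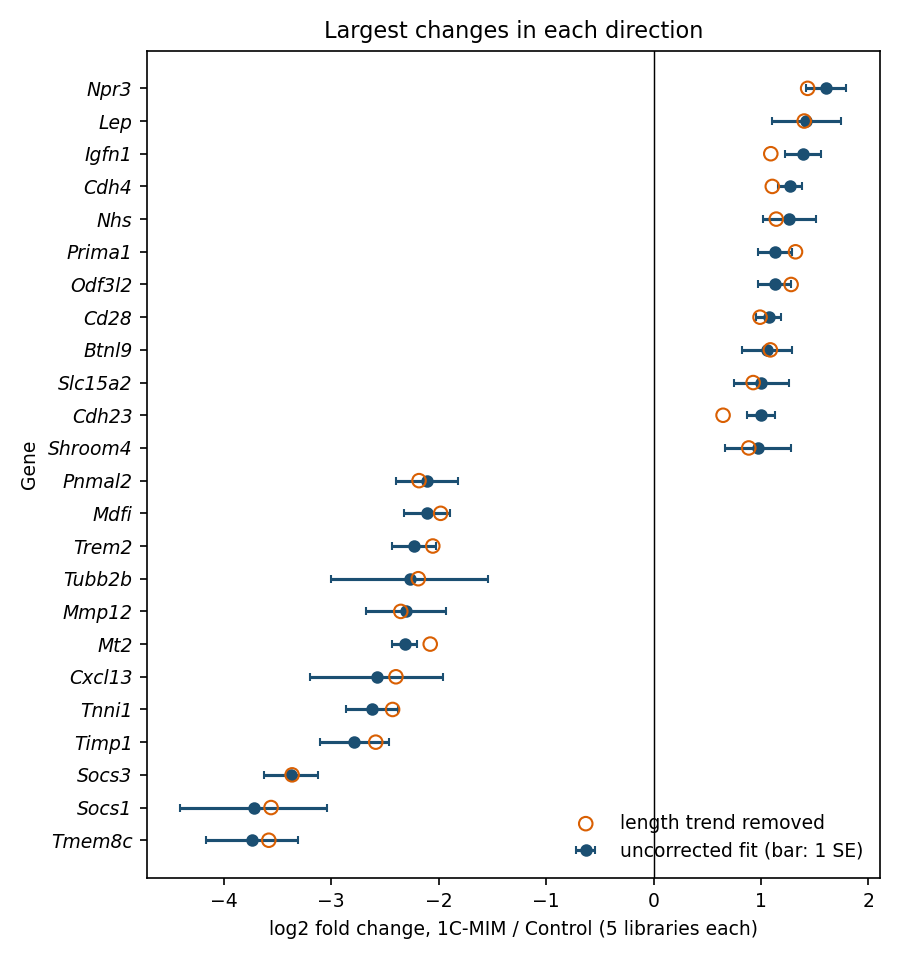
Filled points give the log2 fold change of 1C-MIM over Control (x axis) with bars of 1 SE for the 12 genes with the largest increase and the 12 with the largest decrease among called genes with all 5 1C-MIM libraries on the same side of the Control mean. Open circles give the value once the trend with transcript length was removed; the range runs from -3.73 for Tmem8c to 1.61 for Npr3.

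The fold changes followed transcript length. In the lowest length decile of the tested genes, with a median transcript of 802 bases, 23 genes were called higher and 395 lower, and the median log2 fold change was -0.21. In the highest decile, with a median of 7525 bases, 400 were higher and 26 lower, and the median was 0.24. Across genes, which are not independent replicates, Spearman's rho between fold change and length was 0.44. For each library, the deviation of log2 expression from each gene's mean over all libraries was regressed on length. The slope, per doubling of length, averaged -0.05 in Control (SD 0.055, n = 5) and 0.05 in 1C-MIM (SD 0.059, n = 5; exact permutation test, two-sided p = 0.024). Such deviations make the group means equal and opposite by construction, so only their difference, 0.1, is informative. The signs do not show whether expression itself fell or rose with length in a group. Without Control 5, whose slope of -0.145 was the lowest, the two-sided exact permutation p was 0.063. Once each library's length trend was removed, an alternative chosen after seeing the data, 1012 genes were higher and 1238 lower, and 1752 genes were called in the same direction in both fits. Because of this trend, values with it removed are given beside the lists described in the following paragraphs.

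**Figure D3:**
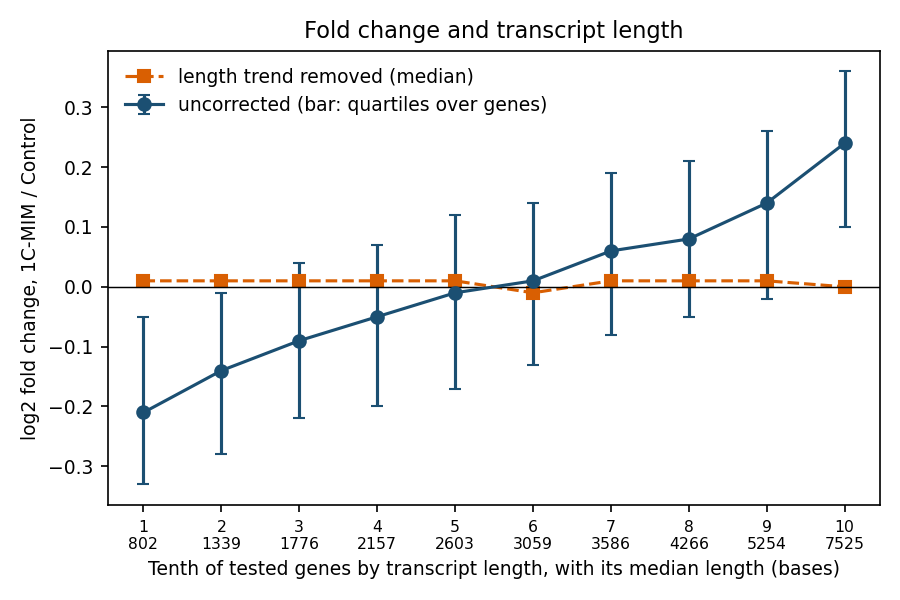
Tested genes are split into deciles by transcript length (x axis, with the median length in bases), and points give the median log2 fold change of 1C-MIM over Control, with bars for the quartiles over genes. The uncorrected medians go from -0.21 in the lowest decile to 0.24 in the highest; squares give the medians once each library's length trend was removed.

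Of 38 gene lists, 37 had enough measured members; 3 were higher and 13 lower in 1C-MIM by camera, which compares a list with all other genes at a preset correlation of 0.01 between members. With a correlation estimated for each list, 0 of these 16 calls held, so each is given with that p as well. By fry, which tests whether the genes of a list move on balance one way and compares them with no other genes, 4 lists were higher and 13 lower. Fry did not call 5 of the camera lists, ribosomal proteins (adjusted p = 0.0606), oxidative phosphorylation (0.0743), methylation enzymes (0.0669), endothelial (0.0517) and interferon response (0.268). It called 6 others, smooth muscle and pericyte, Schwann cell and nerve and muscle atrophy genes as higher and integrated stress response, NAD and creatine and glucocorticoid genes as lower (adjusted p = 0.0311 to 0.0406). With the length trend removed, camera gave 7 higher and 11 lower, and without Control 5 or without 1C-MIM 2 it gave 6 higher. With other splits of the 10 libraries, up to 9 lists were higher in the set of 5 with more 1C-MIM libraries. The count of 3 higher lists thus does not set the real split apart, and chance cannot be excluded for it. The other splits keep part of the real grouping, so their counts are not those of chance alone.

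**Figure D4:**
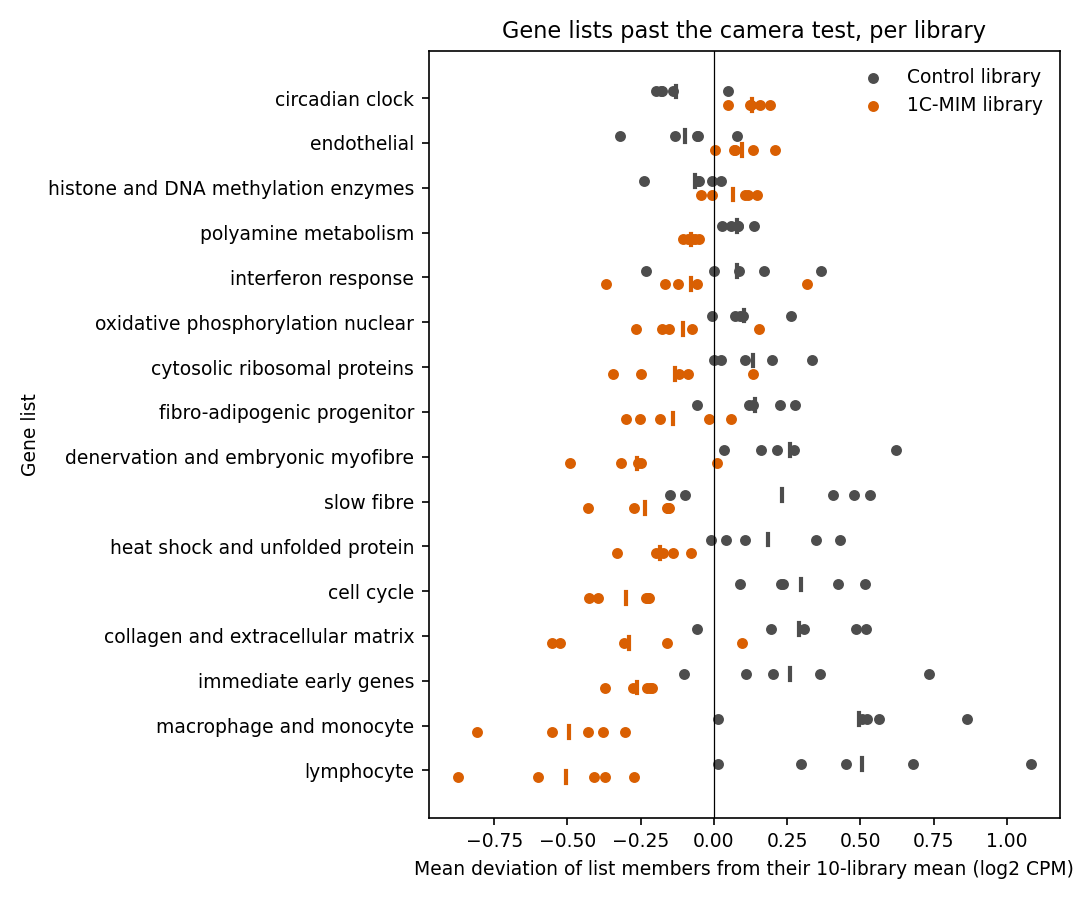
For each list past the camera test (y axis), points give the mean deviation of its members from their 10-library mean (log2 CPM, x axis) in each Control and 1C-MIM library, and vertical ticks give the means of each group. For macrophage genes all 5 Controls (0.014 to 0.865) lie above all 5 1C-MIM libraries (-0.81 to -0.302).

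Among immune cell lists, those of macrophages and lymphocytes were called lower by camera at the preset correlation, but not with an estimated correlation (adjusted p = 0.444 for both). The 6 measured genes of granulocytes and mast cells did not move as a list (0 higher, 1 lower, also when adjusted over the list alone; camera adjusted p = 0.867, and 0.439 with the length trend removed). Of 25 macrophage and monocyte genes, 0 were higher, 22 lower and 3 not past the test, with 22 lower when adjusted over the list alone and a median log2 fold change of -1.08. Ctss, the lysosomal protease cathepsin S, fell by 1.74 (SE 0.13), Ms4a7 by 1.76 (SE 0.17) and Trem2 by 2.23 (SE 0.21), with no overlap between the groups. The list passed camera (adjusted p = 3.1e-13; adjusted p = 0.444 with an estimated correlation), and 20 members stayed lower with the length trend removed. Among 11 measured of 23 lymphocyte genes, 7 were lower and 4 not past the test (9 lower when adjusted over the list alone; median -1.27). Cd52 fell by 1.35 (SE 0.18), the T-helper co-receptor gene Cd4 by 1.61 (SE 0.30) and the antibody joining chain gene Igj (current symbol Jchain) by 1.80 (SE 0.35). The lymphocyte list had camera adjusted p = 4.75e-05, and adjusted p = 0.444 with an estimated correlation; with the length trend removed, 6 members were lower (median -1.10). The interferon response list had 6 of 32 members lower, 0 higher and 26 not past the test (6 lower when adjusted over the list alone; median -0.21), with H2-D1 at -0.42 (SE 0.09), Oas1a at -0.94 (SE 0.21) and B2m at -0.31 (SE 0.09). Its camera adjusted p was 0.0364 (adjusted p = 0.778 with an estimated correlation), 0.104 without 1C-MIM 1, 0.153 without 1C-MIM 2, 0.192 without Control 3, 0.0733 without Control 4 and 0.0782 with the length trend removed, when 2 members were lower. By fry its adjusted p was 0.268. The call of B2m was also lost with that trend removed (-0.10, SE 0.08, edgeR adjusted p = 0.405) and without Control 3, Control 5, 1C-MIM 2 or 1C-MIM 4 (adjusted p = 0.0531 to 0.0596).

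Of 32 collagen and matrix genes, 0 were higher, 19 lower and 13 not past the test (21 lower when adjusted over the list alone; median -0.50). The fibrillar collagen gene Col3a1 fell from 316 ± 78.8 to 108 ± 17.6 CPM (SD, n = 5 per group; log2 fold change -1.56, SE 0.17), the matricellular protein gene Postn fell by 1.41 (SE 0.20) and Timp1 by 2.78 (SE 0.32). The matrix list had camera adjusted p = 8.75e-09 (adjusted p = 0.545 with an estimated correlation), and 23 members were lower with the length trend removed. In the list of fibro-adipogenic progenitors, the connective tissue cells of muscle, 0 of 16 genes were higher, 7 lower and 9 not past the test; adjusted over the list alone, 1 was higher and 8 lower. Its median was -0.29, with Thy1 at -0.69 (SE 0.11), Lum at -0.46 (SE 0.09) and Mfap5 at -0.70 (SE 0.14), and camera gave adjusted p = 0.00771 (adjusted p = 0.545 with an estimated correlation). Its lower members were 4 with the length trend removed, and the median was -0.16 (camera adjusted p = 0.00956). Matrix scores did not separate the groups in full, since Control 2 (-0.057) lay below 1C-MIM 2 (0.096).

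In the denervation and embryonic myofibre list, 10 of 23 genes were lower, 1 higher and 12 not past the test (11 lower and 1 higher when adjusted over the list alone; median -0.29). Besides Tmem8c, the myogenic factor Myod1 fell by 0.59 (SE 0.09) and the embryonic light chain gene Myl4 fell too (-1.71, SE 0.26). The member that rose, chosen after its value was seen, was Hdac4 (0.70, SE 0.17), a histone deacetylase induced by denervation. For this list camera adjusted p was 0.00331 (adjusted p = 0.545 with an estimated correlation) and 0.00101 with the length trend removed. Of 13 slow fibre genes, 0 were higher, 5 lower and 8 not past the test (6 lower when adjusted over the list alone; median -0.35), among them Tnni1, Tnnt1, the slow troponin T (-1.05, SE 0.18), and Tpm3, the slow tropomyosin (-0.41, SE 0.09). The slow fibre list had camera adjusted p = 0.00947 (adjusted p = 0.444 with an estimated correlation), and 5 members were lower with the length trend removed (median -0.26). Its scores were higher in Control 3, Control 4 and Control 5 (0.406 to 0.534) than in Control 1 (-0.098) and Control 2 (-0.149), which lay close to the highest 1C-MIM library (-0.154).

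Of 25 immediate early genes, which respond within minutes to stimuli, 12 were lower, 1 higher and 12 not past the test (15 lower and 1 higher when adjusted over the list alone; median -0.57). Junb fell by 1.29 (SE 0.09, edgeR adjusted p = 7.54e-06), Fos by 1.79 (SE 0.20) and Egr1 by 1.08 (SE 0.21), while Jun, chosen after its value was seen, rose by 0.16 (SE 0.05). The list had camera adjusted p = 2.57e-05 (adjusted p = 0.444 with an estimated correlation), its score was highest in Control 1 (0.734), and 11 members were lower and 1 higher with the length trend removed (median -0.52). For heat shock and unfolded protein genes, 12 of 21 were lower, 0 higher and 9 not past the test (14 lower when adjusted over the list alone; median -0.38). Sdf2l1 fell by 0.87 (SE 0.10), the unfolded protein response factor Xbp1 by 0.39 (SE 0.05) and the disulfide isomerase Pdia6 by 0.52 (SE 0.08), with camera adjusted p = 1.98e-07 (adjusted p = 0.444 with an estimated correlation). Removing the length trend left 10 lower (median -0.33). In the cell cycle list, 12 of 21 measured genes were lower, 1 higher and 8 not past the test (13 lower and 1 higher when adjusted over the list alone; median -0.46). Top2a fell by 1.76 (SE 0.22), Mcm5 by 0.66 (SE 0.14) and Birc5 by 1.44 (SE 0.31). Levels were low for Top2a (1.70 CPM in Control, 0.498 in 1C-MIM) and Birc5 (0.539 and 0.196). Rrm1, a ribonucleotide reductase subunit chosen after its value was seen, rose by 0.20 (SE 0.06). That call was lost with the length trend removed (0.13, SE 0.06, edgeR adjusted p = 0.117). The cell cycle list had camera adjusted p = 4.75e-05 (adjusted p = 0.444 with an estimated correlation), and 10 members were lower and 0 higher with the length trend removed (median -0.44).

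Of 75 cytosolic ribosomal protein genes, 0 were higher, 33 lower and 42 not past the test (45 lower when adjusted over the list alone), with a median of -0.25, and Rps16, Rps14 and Rpl17 were at -0.44 each (SE 0.08, 0.09 and 0.09), and at -0.21, -0.21 and -0.23 with the length trend removed. The camera adjusted p was 2.32e-11 (adjusted p = 0.552 with an estimated correlation), and that of fry 0.0606. With the length trend removed the median was -0.05, 2 members were higher and 8 lower, and camera adjusted p was 0.0392; with GC content removed too it was 0.0931. Of 76 nuclear genes of oxidative phosphorylation, 0 were higher, 22 lower and 54 not past the test (25 lower when adjusted over the list alone; median -0.21), with Cox7a1 at -0.43 (SE 0.09), Atp5e at -0.40 (SE 0.10) and Atp5j2 at -0.36 (SE 0.09), each with overlapping groups. That list had camera adjusted p = 9.18e-09 (adjusted p = 0.596 with an estimated correlation) and fry adjusted p = 0.0743, and camera gave 0.87 with the length trend removed, when 2 members were higher and 4 lower. The call of Atp5j2 ended there (-0.11, SE 0.04, edgeR adjusted p = 0.111). Those of Cox7a1 (-0.14, adjusted p = 0.066) and Atp5e (-0.12, adjusted p = 0.108) ended with length and GC content removed.

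Of 20 circadian clock genes, 10 were higher, 0 lower and 10 not past the test (10 higher when adjusted over the list alone; median 0.28). The period gene Per2 rose by 0.57 (SE 0.09), the clock output factor Hlf by 0.50 (SE 0.08) and the repressor Cry2 by 0.36 (SE 0.06), with no overlap between the groups. The clock list passed camera at adjusted p = 5.93e-05 (adjusted p = 0.0938 with an estimated correlation). With the length trend removed camera adjusted p was 0.00319, 8 members were higher and the median was 0.17. The clock score of Control 1 (0.05) lay above the other Controls (-0.20 to -0.14), and the time of day of collection is not given in the sources used here. In the endothelial list, 8 of 16 genes were higher, 1 lower and 7 not past the test (9 higher and 1 lower when adjusted over the list alone; median 0.23). The receptor genes Flt1 and Eng rose by 0.50 (SE 0.11) and 0.27 (SE 0.06), and Vwf, the von Willebrand factor gene, by 0.53 (SE 0.13), while Aplnr, chosen after its value was seen, fell by 0.40 (SE 0.12). The endothelial list had camera adjusted p = 0.00947 (adjusted p = 0.545 with an estimated correlation), 0.0816 without Control 1, whose score of -0.32 was the lowest, and 0.0517 by fry. With the length trend removed, 5 members were higher and 1 lower (median 0.22, camera adjusted p = 0.00264). The call of Vwf was lost with the length trend removed (0.24, SE 0.10, edgeR adjusted p = 0.122), and Flt1 was then at 0.33.

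Of 37 measured genes of the folate and methionine cycle, 3 were higher, 6 lower and 28 not past the test, and the same counts held when adjusted over the list alone (median -0.02; camera adjusted p = 0.448). Mthfd2, the mitochondrial folate dehydrogenase, fell from 8.20 ± 0.877 to 4.72 ± 0.548 CPM (SD, n = 5 per group; log2 fold change -0.80, SE 0.11, edgeR adjusted p = 0.000497). Its cytosolic counterpart Mthfd1 rose by 0.29 (SE 0.05, edgeR adjusted p = 0.0027), and Gamt, which makes creatine and consumes S-adenosylmethionine, fell by 0.76 (SE 0.14, edgeR adjusted p = 0.00388). By fry's mixed test, which asks for change in either direction, the list had adjusted p = 1.39e-06. This does not set it apart, since all lists but the fatty acid oxidation, tendon, erythroid and granulocyte lists passed the mixed test. Adipocyte genes had the same mixed adjusted p (1.39e-06) and glucocorticoid genes a smaller one (4.59e-08). Removal of the length trend gave 2 higher and 4 lower (median -0.02, camera adjusted p = 0.608). Serine synthesis, transsulfuration and glutathione genes split evenly, with 3 of 24 higher, 3 lower and 18 not past the test, and the same when adjusted over the list alone (median -0.01; camera adjusted p = 0.754). The glutathione peroxidase genes Gpx1 and Gpx4 fell by 0.59 (SE 0.09) and 0.35 (SE 0.09), and the cysteine dioxygenase gene Cdo1 fell by 0.53 (SE 0.15). The 3 members that rose, chosen after their values were seen, were the peroxidase gene Gpx3 (0.23, SE 0.07), the most abundant of these with 337 CPM in Control and 395 in 1C-MIM, and the glutathione transferase genes Gstm1 (0.24, SE 0.08) and Gstm2 (0.43, SE 0.13). With the length trend removed, 5 members were higher and 1 lower, the median was 0.09, and the test turned towards higher (camera adjusted p = 0.11). With the length trend removed, the call of Gpx4 was lost with a smaller fold (-0.17, SE 0.06, edgeR adjusted p = 0.0582). That of Cdo1 was lost with most of its fold kept (-0.41, SE 0.14, adjusted p = 0.0738), and also without Control 5, 1C-MIM 3 or 1C-MIM 4 (adjusted p = 0.0531, 0.0501 and 0.0641).

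Polyamine genes had 3 of 18 members lower, 0 higher and 15 not past the test (3 lower when adjusted over the list alone; median -0.15), with Sat1 at -0.36 (SE 0.09), Smox at -0.53 (SE 0.14) and Odc1, the first enzyme of polyamine synthesis, at -0.24 (SE 0.07), each with overlapping groups. Camera gave adjusted p = 0.0224 (adjusted p = 0.444 with an estimated correlation) and 0.195 with the length trend removed (2 members lower, median -0.07), when the call of Sat1 was also lost (-0.20, SE 0.08, edgeR adjusted p = 0.102). That of Smox was lost there too, although its fold stayed similar (-0.48, SE 0.15, edgeR adjusted p = 0.0577). The call of Odc1 was lost when any of 8 single libraries was left out, with adjusted p of up to 0.0959, and that of Smox without Control 5 (adjusted p = 0.0516). Histone and DNA methylation enzymes, which use S-adenosylmethionine or reverse its marks, had 12 of 47 genes higher, 2 lower and 33 not past the test, and the same when adjusted over the list alone (median 0.13). The DNA demethylase gene Tet2 rose by 0.62 (SE 0.13; 0.34 with the length trend removed), while the methyltransferase gene Prmt1 fell by 0.22 (SE 0.05) and Uhrf1, a partner of Dnmt1, fell by 1.38 (SE 0.34). Camera gave adjusted p = 0.0041 towards higher (adjusted p = 0.545 with an estimated correlation) and fry 0.0669, but with the length trend removed the test turned towards lower (adjusted p = 0.87) with 3 members higher, 4 lower and a median of 0.02, so the test and the median then differed in sign. The call of Prmt1 was also lost there (-0.09, SE 0.04, edgeR adjusted p = 0.153). That of Uhrf1 was lost without Control 1 and Control 5 (-0.87, adjusted p = 0.0678). The Y-linked genes of the sex check gave 0.30 for Ddx3y (SE 0.10, edgeR adjusted p = 0.0434) and 0.44 for Kdm5d (SE 0.13, 0.0242). They gave 0.41 for Uty (SE 0.15, 0.0648) and 0.01 for Eif2s3y (SE 0.10, 0.951), and the groups overlapped for all 4. The calls of Ddx3y and Kdm5d were lost with library totals (adjusted p = 0.14 and 0.0632), and each without 1C-MIM 2, 1C-MIM 3 or 1C-MIM 4 (adjusted p = 0.0546 to 0.103). Ddx3y was also lost without Control 3, Control 4 or 1C-MIM 1 (adjusted p = 0.0517 to 0.0812) and with 1 surrogate variable (adjusted p = 0.0582). It was lost again with the trend of length (0.21, SE 0.07, adjusted p = 0.0649) or of length and GC content (0.12, adjusted p = 0.133) removed. The call of Kdm5d was lost with length and GC content removed (0.27, adjusted p = 0.0539).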

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

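The tests of transcript length, of muscle dilution, of library numbers and of both sources of neural transcripts were chosen after the results were seen. In 240 groups of 5 values, 18 had a library far from the other 4 of its group, where chance sets a library apart in about 1 in 20 groups, 12 here. Of these values, 7 were in Control 1, 4 in Control 2, 1 in Control 3, 5 in Control 5 and 1 in 1C-MIM 5.

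In log2 CPM, Control 1 was high for Tubb2b (4.0, other Controls 0.65 to 1.37) and low for Mt2 (5.13, others 5.61 to 5.71), Myod1 (4.91, others 5.19 to 5.25), Smox (8.65, others 9.19 to 9.24) and Odc1 (6.76, others 6.94 to 6.98). Control 2 was high for Lep (4.13, others 3.21 to 3.41) and Btnl9 (0.99, others 0.01 to 0.25) and low for Fos (2.92, others 3.92 to 4.21). Control 3 was low for Xbp1 (6.53, others 6.59 to 6.61). Control 5 was low for Shroom4 (-0.57, others 1.21 to 1.41) and Uty (2.1, others 2.67 to 2.89), and 1C-MIM 5 was high for Socs3 (1.77, other 1C-MIM libraries 1.35 to 1.41). Among list scores, Control 1 stood apart for cholesterol and fatty acid synthesis (0.24, others -0.02 to 0.04) and for the circadian clock (0.05, others -0.20 to -0.14), Control 2 for granulocytes and mast cells (-0.36, others 0.02 to 0.15) and Control 5 for serine, transsulfuration and glutathione genes (0.10, others -0.03 to -0.01). Of the library quantities, Control 5 had a larger share of counts in its 10 most abundant genes (29.5%, others 27.0 to 27.3%). Its deviations from the gene means also had a steeper slope on transcript length (-0.145, others -0.049 to -0.013).

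Fold changes followed transcript length, with long transcripts higher in 1C-MIM. With each library's trend removed, the total of calls was 75% of the total before, and 53.9 to 93.3% when single libraries were left out. This compares totals and not the same genes: 1752 genes were called in both fits, 1247 only without the removal and 498 only with it. The test took 75% or more as a sign against the trend as the cause and under 50% as a sign for it, bounds written after the trend had been seen and before it was removed, and the spread covers values on both sides of 75%, so a length-dependent technical difference and a real difference in long and short transcripts cannot be told apart for the calls as a whole. A candidate explanation is RNA fragmentation, which no label reports.

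Of the macrophage, matrix and embryonic myofibre lists, 22 of 25, 19 of 32 and 10 of 23 members were lower in 1C-MIM, and none of the lists passed camera with an estimated correlation (adjusted p = 0.444, 0.545 and 0.545). The tables argue against the length trend as the whole cause, since the macrophage median was -0.90 with the trend removed, the matrix median -0.57 and the embryonic median -0.37, and 48 of their 51 lower calls were kept. They also argue against Control libraries with merely less myofibre RNA, but only as a shift shared by all non-myofibre cells. The median of 42 endothelial, smooth muscle and Schwann cell genes was 0.18, and that of 25 macrophage genes -0.90, a difference of 1.08. These lists were picked after the results were seen. The permutation test across genes (p = 1e-05, the smallest that 100000 resamples give) treats genes of a list as independent, which they are not, and does not measure spread between animals. Other non-myofibre lists went both ways with the trend removed, with medians of -1.1 for lymphocytes, -0.16 for fibro-adipogenic progenitors, 0.02 for adipocytes and 0.2 for granulocytes and mast cells. Handling stays open: each of the 2 series of animal numbers holds both groups, and with the series as a block 1324 genes were higher and 1500 lower, but the running library numbers at the end of the deposited names form a run for each group, with 0 libraries in the other group's run, so library handling and supplement cannot be told apart. An effect of the supplement, and a difference between the groups in how the injury elsewhere in the body acted on the quadriceps, may also account for it and were not tested.

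Control 1 held neural transcripts. A list of 25 brain neuron markers was written after the pattern was seen. Of these, 100% had their highest CPM in Control 1 by library totals without TMM factors, where chance gives 10%. Camk2a was highest there only by library totals, and its reads were not raised (16927 in Control 1 against 15170 to 17588 elsewhere). Of the 25, 4 reached 1 CPM in at least 1 other library, 3 of them in the mean of the other 9. Tubb3 had 301 reads against 17 to 50 elsewhere, Dcx 113 against 0 to 10 and Gap43 104 against 1 to 4, and of 13 glia and neural progenitor markers 9 were highest in Control 1, with Fabp7 at 96 against 0 to 3, Ptprz1 at 69 against 7 to 19 and Slc1a2 at 26 against 2 to 9, but Gfap at 1 against 0 to 7. More peripheral nerve in that sample is argued against by the 13 measured of 17 Schwann cell and nerve genes. Their mean lay 0.17 below that of the other Controls (difference -0.17, SD of those 4 0.054), with Mbp at 438 reads against 570 to 845. Nefl and Nefm belong to that list, but they had too few reads outside Control 1 to be measured, so the difference leaves them out. A list of 10 nerve genes that keeps them, nearly all from the same list, lay 0.44 above the other Controls. That rise came through Nefl (33 reads in Control 1) and Nefm (35), which neurons of the brain also express. A small admixture of brain RNA or reads may account for the neural transcripts, and no test says how it arose.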

How the results depend on the processing

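Removing the trends with length or with length and GC content and leaving out Control 1 and Control 5 together were chosen after seeing the data. None of the 76 named genes past the threshold turned direction under any alternative in which it was compared. The filter of 1 CPM covered 74 of the 78, DESeq2 77 and the fit without sex-linked genes 74. Single genes were not compared with each transcript tested alone. Of all 78, 20 changed their side of the threshold in at least 1 alternative. Of these, 8 lost their call when a single library was left out and 11 with the length trend removed, and Uty gained a call without Control 1 or 1C-MIM 1. With 1 surrogate variable 7 named genes lost their call, and without Control 1 and Control 5 together 11 did. The cause was not tested, except where a stricter threshold brings fewer calls by construction. Fewer libraries did not always bring fewer calls: without 1C-MIM 1, 1558 genes were higher and 1885 lower. Library totals gave 606 genes higher and 2896 lower. Voom with quality weights gave 2166 higher, an adjusted p under 0.1 gave 2114, and a fold of at least 1.5 gave 193 higher and 537 lower. Without Control 1 and Control 5, 832 were higher and 976 lower. With single libraries left out, 739 to 1558 genes were higher and 941 to 1885 lower, and 3 to 6 lists higher and 12 to 14 lower, against 1357, 1642, 3 and 13. Control 4 (902 higher), 1C-MIM 3 (843 and 1057) and 1C-MIM 4 (739 and 941) moved the gene counts by over 1.5 times, and Control 5 and 1C-MIM 2 the higher lists (6 each). An estimated correlation left 0 lists higher and 0 lower, with or without the length trend. Removing length, or length and GC content, gave 7 lists higher. Oxidative phosphorylation turned towards higher with length and GC content removed (camera adjusted p = 0.989), and histone and DNA methylation enzymes towards lower with length removed (0.87; 0.954 with an estimated correlation) and with length and GC content removed (0.989); without the estimated correlation the alternatives for these lists reached up to 0.989. The variance share was 34.6 to 40.7% with single libraries left out. With replicate number as a block it was 56.6% (exact permutation p = 0.062, the smallest that 32 swaps allow), 1932 genes were higher and 1965 lower, and the calls of Lep and Tubb2b were lost while Uty and the smooth muscle list passed. Equal numbers did not mark pairs clearly: same-number correlations were -0.08 to 0.39, and 4 of 10 libraries matched their own number best. With the series of animal numbers as a block, 1324 genes were higher and 1500 lower, and all 37 lists kept their side of the threshold. DESeq2 gave 1795 higher and 1806 lower, and limma-voom 1395 and 1629. A block for sex was not run, since the libraries showed a single pattern. Depth limits genes of low counts, such as Tmem8c with a 1C-MIM mean of 0.308 CPM. The genes named from lists had no floor of expression beyond the filter. Among them, the 1C-MIM means of Birc5, Cd4 and Uhrf1 were 0.196, 0.324 and 0.369 CPM.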

Other observations

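The tests of lists and splits given here were planned, except those with the length trend removed and the split test of lists higher, which were added after the data were seen, and the single genes named here were chosen after their values were seen. Fast fibre genes had 6 of 16 members higher and 0 lower (7 higher and 4 lower when adjusted over the list alone), with Mylk2 at 0.48 (SE 0.07), Actn3 at 0.45 (SE 0.08), Myh1 at 0.42 (SE 0.09) and Myh4 at 0.32 (SE 0.07), but the median was -0.01 and the list did not pass (camera adjusted p = 0.232); with the length trend removed the calls of Myh1 (0.26, SE 0.08, edgeR adjusted p = 0.05) and Myh4 (0.15, SE 0.07, adjusted p = 0.181) were lost. Of 25 muscle atrophy and autophagy genes, 8 were higher and 1 lower (9 and 2 when adjusted over the list alone), including Foxo3 (0.67, SE 0.20), Txnip (0.62, SE 0.11) and Mstn, the growth inhibitor myostatin (0.48, SE 0.15; 0.49, SE 0.16 with the length trend removed, when its call was lost, edgeR adjusted p = 0.0586), with camera adjusted p = 0.0914. Of 24 cholesterol and fatty acid synthesis genes, 9 were lower and 1 higher (10 and 2 when adjusted over the list alone), among them Sqle (-0.60, SE 0.15) and Cyp51 (-0.54, SE 0.11), while Srebf1 rose by 0.29 (SE 0.07), with camera adjusted p = 0.0678. With the length trend removed 6 lists gained a camera call: fast fibre (adjusted p = 0.00429), atrophy (0.0145), cholesterol (0.00277), fatty acid uptake and oxidation (0.00319), TCA cycle (0.00917) and Schwann cell and nerve (0.0405). With an estimated correlation as well, none of the 6 passed (adjusted p = 0.376 to 0.588).

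Glucocorticoid response genes went both ways, with 5 of 18 higher and 3 lower (6 and 3 when adjusted over the list alone; camera adjusted p = 0.754, and 0.822 with the length trend removed). Zbtb16 rose by 0.87 (SE 0.16) and Klf9 by 0.50 (SE 0.12), while the metallothionein Mt1 fell by 1.94 (SE 0.11, edgeR adjusted p = 1.01e-06), and Lcn2 fell by 1.42 (SE 0.25). Nmrk2, a nicotinamide riboside kinase of muscle, fell from 396 ± 37.3 to 147 ± 28.7 CPM (SD, n = 5 per group; log2 fold change -1.44, edgeR adjusted p = 4.22e-05). In the senescence list, 4 of 18 genes were lower and 2 higher (the same when adjusted over the list alone; camera adjusted p = 0.705, and 0.778 with the length trend removed), with Cdkn2a at -1.56 (SE 0.32), Ccl2 at -1.31 (SE 0.25) and Igfbp3 at 0.70 (SE 0.09). The imprinted neighbours Igf2 (-1.24, SE 0.18) and H19 (-1.26) were both lower. The oxidative stress gene Hmox1 was at -0.84 (SE 0.10), and the adipocyte genes Cfd and Adrb3 at -0.82 (SE 0.09) and -0.84 (SE 0.18), in a list of 22 with 2 higher, Lep among them, and 5 lower (2 and 6 when adjusted over the list alone) that did not pass (camera adjusted p = 0.641, and 0.87 with the length trend removed). Among other lists that did not pass without that removal, smooth muscle and pericyte genes had 3 of 13 higher and 0 lower (6 higher when adjusted over the list alone; camera adjusted p = 0.0678, and 0.191 with the length trend removed), and Schwann cell and nerve genes 2 of 13 higher and 1 lower (5 and 1 when adjusted over the list alone; camera adjusted p = 0.0852). Further, fatty acid uptake and oxidation genes had 2 of 32 higher and 0 lower (0 and 0 when adjusted over the list alone; 0.0951) and TCA cycle genes 1 of 20 higher and 0 lower (0 and 0 when adjusted over the list alone; 0.315).

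Other splits of the 10 libraries, 100 in all with the real one among them, tested the counts of calls. Only 1 of the 100, the real one, gave as many genes higher (1357) and as many lower (1642). Another split gave at most 2 genes in 1 direction. The share of 1 in 100 is the smallest these splits allow, and it makes chance an unlikely source of both counts. For lists lower in 1C-MIM, 2 of the 100 gave at least 13 in their larger direction, the highest other being 13. That share makes chance unlikely for this count but does not exclude it, since another split reached the same count. With an estimated correlation, 0 lists were lower. For lists higher, counted in the set of 5 with more 1C-MIM libraries, 75 of the 100 gave at least 3, the highest other being 9, so chance cannot be excluded for that count, and camera with the preset correlation called lists in other splits too. By fry, the real split gave 17 lists and the highest other 6.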
